A study of Drosophila melanogaster with 9 samples.

How the data were processed

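Small RNA libraries from adult midguts of wild-type Oregon-R flies (Drosophila melanogaster) were analysed in 9 samples, which the labels place in 3 groups of 3. The mock group was fed sucrose and sampled at day 0. The other groups received the treatment written as Pe in the labels, which do not spell out the abbreviation, and were sampled at day 0 and at day 3. Flies of the mock and Pe day 0 groups were 4 to 5 days old and those of the Pe day 3 group 7 to 8 days old, per the labels. Per the labels' protocols, total RNA was extracted with TRIzol and 2 µg entered the Illumina TruSeq small RNA library kit. The labels do not say whether the 3 samples of a group came from separate pools of flies, so the p-values measure the spread between these samples, which may be technical.

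The deposited expression table gives RPM (reads per 1000000 miRNA reads) for 467 miRNAs, of which 145 were listed above 0, and each column sums to that total. The name of the deposited table mentions the tool miRge, which assigns small RNA reads to known miRNAs. The aligner, the miRNA database release and the genome build were not given in the sources used here. The authors' deposited table of comparisons holds a mean signal per miRNA over the 9 libraries, log2 fold changes with standard errors, a test score (the Wald statistic) and p-values with adjusted p-values. Its column names, per the file headers, are those of DESeq2, and version 1.22.0 of DESeq2 is named in the submitters' processing notes. The headers of that deposited table do not name its 2 contrasts. The first set of log2 fold changes matched Pe day 0 over mock and the second Pe day 3 over mock, with a largest difference of 0.033 and 0.045 over the 47 miRNAs whose deposited mean exceeded 50.

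The design written before the data were examined assumed whole-number counts. The deposited values are RPM and the reads recovered from them did not meet the rule given below, so the planned quasi-likelihood count test and the planned DESeq2 alternative were not run, and limma on log2 values took their place. The authors' deposited table stands beside it for the contrasts it holds. The RPM values were whole multiples of a step that differed between libraries, within 1.27e-06 of a whole number. The smallest listed value was 2 reads in every library, so a miRNA listed at 0 may have had 1 read. The reads recovered in this way gave library totals of 224873 to 1238105 and matched the deposited mean signal to a relative difference of 4.44e-15. The rule set for accepting recovered reads in a count test asks for more low values per library than these libraries have. The planned count tests were therefore not run on them, although they matched the deposited mean, and limma voom was the 1 test run on them. They were also used for depths and scaling.

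Libraries were scaled with trimmed mean of M values (TMM) factors, trimming 30% of log ratios and 5% of abundances. The filter kept miRNAs with at least 20.1 RPM, or 10 reads at the median depth of 497997, in at least 3 libraries, which left 73 miRNAs with 99.96% of the reads. Values were tested as log2(scaled RPM + 4.02), a pseudocount of 2 reads at the median depth. Fold changes are on that scale, which understates the change of scarce miRNAs. One limma model (version 3.58.1 in R 4.3.3, with trended and robust empirical Bayes variances) held all 9 libraries, with 6 residual degrees of freedom and no block. Benjamini-Hochberg adjusted p under 0.05 was the threshold for a call, in each of 3 contrasts and in a joint F test among the 3 groups. Standard errors are from limma and SDs are over the 3 libraries of a group. Counting intervals were not attached to reads, since PCR copies are not independent molecules.

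For 15 lists of hairpins fixed with the design, limma's camera test compared the more abundant arm of each hairpin with all other hairpins, with a preset correlation of 0.01, where at least 3 members were tested. The estimated correlation and limma's fry test stood beside it. fry was run on TMM values only and tests a list against no change, so a shift of all miRNAs enters its p. The lists were the let-7 complex, the miR-277, miR-9c and miR-12 clusters, midgut progenitor, immunity, metabolism and growth, sensory organ and proneural, the K box and miR-92 seed families, and markers of neurons, muscle, ovary, early embryo and testis. Some lists overlap. The immunity list holds the whole miR-277 cluster, and miR-277 is also in the midgut progenitor and the metabolism and growth lists. The miRNAs named were chosen by a rule fixed with the design. It took called miRNAs whose libraries did not overlap between groups and whose mean was at least 10 RPM in a group, up to the 10 largest rises and 10 largest falls per contrast. It added the 5 most abundant miRNAs, both arms of miR-958 (which outside reports tie to the midgut stress response), and up to 4 members with the smallest p from each list. Whether those reports on miR-958 used these same libraries was not checked, so that choice may not be independent of the data. Other miRNAs are named as chosen after their values were seen.

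The replicate numbers in the labels were checked for pairing by correlating the deviations of same-numbered libraries from their group means. For Pe day 0 and mock the correlations were 0.24, 0.43 and 0.36, all above 0.1, so those numbers may pair the libraries. This pairing comes from the data and not from a label. The main model held no block and so left it aside, and models with the number as a block are given beside it. For Pe day 3 and Pe day 0 they were 0.22, 0.17 and -0.26, and for Pe day 3 and mock -0.01, 0.08 and -0.02. Libraries of one group differed by more than sampling noise, with a chi-square per degree of freedom of 14.4 to 116, so none was a second listing of the same reads. That measure covers counting error only and does not tell separate pools from repeated libraries of 1 pool.

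The model was tested on simulated data for Pe day 0 against mock, in 100 simulations with a median of 76 miRNAs tested and 20 changed. It recovered 64.1% of 2-fold changes and 90.8% of 4-fold changes, and 3.67% of calls were false. Simulations without any change gave 0.06 calls on average. Each miRNA was drawn independently around the TMM-scaled depth, without deviations shared within a library or between same-numbered libraries. These rates may therefore be too favourable for the real contrast. The relation of the changes against mock was set beside 1000 simulations without an effect, which also drew each miRNA independently. Alternatives tried were median-of-ratios factors, RPM as deposited, the total without the 5 most abundant miRNAs, limma voom, no filter and a filter of 10 RPM, only the groups compared, a replicate block and leaving out each library. For the lists, all arms of each hairpin were also used. The filter of 10 RPM was planned as the stricter one but is laxer than the main filter in RPM. Pseudocounts of 1 and 20 RPM, a filter of 100 RPM, a replicate block in only the groups compared, and within-library ratios were added after the data were seen.

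Hairpin positions were taken from the Ensembl release 115 annotation of genome build BDGP6.54 by name, which matched 260 of 262 hairpins. The miR-281-1 and miR-281-2 hairpins are near-identical copies, so reads assigned to one or the other are uncertain. The rows miR-2a-3p/2c-3p and miR-276a-5p/276b-5p join 2 names each. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.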

Results

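The series examined how midgut regeneration starts and ends in adult flies, with miRNAs measured by small RNA sequencing in mock, Pe day 0 and Pe day 3 midguts. Each group held 3 libraries. The miRNA reads per library, recovered from the deposited RPM, were 707747, 363095 and 497997 in the mock group. They were 809842, 296702 and 1238105 at Pe day 0, and 864119, 399569 and 224873 at Pe day 3. A single miRNA, miR-956-3p, made up 69.8% to 80.2% of the reads of a library. Together with miR-10-5p, miR-184-3p, miR-263a-5p and miR-31a-5p it took 92.9% to 96.2%. The miR-956 hairpin lies on chromosome 3L from 11773731 to 11773878 on the minus strand, outside other annotated genes. miR-263a is known to limit sodium channel subunits in the fly gut.

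Other cell types and tissues left small traces. The muscle markers miR-1 and miR-133 summed to 64.2 to 140 RPM in the mock and Pe day 0 libraries and to 267 to 382 RPM in the Pe day 3 libraries, all of it miR-1-3p except 2 reads of miR-133-3p in Pe day 0 replicate 3. The neuronal list summed to 0 to 14.8 RPM, the early embryo list to 0 to 33 RPM and the testis list to 0 to 17.8 RPM. The ovary list summed to 129 RPM in Pe day 0 replicate 3 and to 0 to 27.5 RPM in the other libraries.

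The scaling moved the middle of the distribution. With TMM the median log2 change over the 73 tested miRNAs was 0.17 for Pe day 0 against mock, 0.01 for Pe day 3 against Pe day 0 and 0.21 for Pe day 3 against mock, and with median-of-ratios factors it was -0.02, 0.04 and 0.05. Changes relative to the TMM median are therefore given as well.

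Pe day 0 was compared with mock day 0, in flies of the same age, to describe the first stage. miR-10404-5p rose 3.60-fold (log2 change 1.85 ± 0.44 SE, 1.68 above the median of all, adjusted p = 0.015), from 9.92 ± 1.45 to 52.1 ± 35 scaled RPM (SD, n = 3). Annotated copies of miR-10404 include 2 within precursor ribosomal RNA. miR-34-3p rose 1.78-fold (log2 change 0.83 ± 0.23 SE, 0.66 above the median, adjusted p = 0.029), from 673 ± 142 to 1183 ± 117. The abundant midgut miRNA miR-281-2-5p fell by 1.06 ± 0.27 SE on the log2 scale, or 2.09-fold (1.23 below the median of all, adjusted p = 0.021), from 1371 ± 382 to 668 ± 231. All 3 libraries of one group lay beyond all 3 of the other for each of these.

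These 3 of 73 miRNAs passed limma's threshold, 2 higher and 1 lower, while 20 had an unadjusted p under 0.05. The libraries of the groups did not overlap for 24 miRNAs, or 32.9%, where chance gives 10%. Median-of-ratios factors called 1 higher and 1 lower, the total without the 5 most abundant miRNAs likewise called 1 and 1, both without miR-34-3p, and RPM as deposited called 0 in limma, with 16 at an unadjusted p under 0.05. The authors' deposited table called 2, both lower, and shared miR-281-2-5p. Its other call, miR-184-3p, had a log2 change of -0.65 there and of -0.45 ± 0.20 SE here (adjusted p = 0.158). With the replicate number as a block, 1 miRNA was called in the model of all 9 libraries, miR-10404-5p, and 11 in a model of only these groups, all 3 above among them. Without the block the model of only these groups also called 11. Leaving out mock replicate 1, mock replicate 2 or Pe day 3 replicate 2 left 0 calls in limma, with 9, 17 and 17 miRNAs at an unadjusted p under 0.05, and leaving out mock replicate 3 left 1. Without Pe day 3 replicate 1 there were 8 calls, and without Pe day 0 replicate 3, the library with the ovary signal, there were 5. miR-281-2-5p also lost its call without Pe day 0 replicate 2, and miR-34-3p without Pe day 0 replicate 2, Pe day 0 replicate 3 or Pe day 3 replicate 3, where 3, 5 and 2 miRNAs were called. In all, miR-34-3p lost its call in 13 of 22 alternatives, miR-281-2-5p in 7 of 22 and miR-10404-5p in 8 of 21, limma voom among the last.

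In the lists, 1 of 5 arms tested in the miR-277 cluster was called, and 3 when adjusted over the list alone. Besides miR-34-3p, miR-34-5p had a log2 change of 0.92 ± 0.33 SE (adjusted p = 0.103), miR-317-3p of 0.86 ± 0.31 (adjusted p = 0.103) and miR-277-5p of 0.83 ± 0.39 (adjusted p = 0.158). The midgut progenitor list had 0 of 12 arms called, and 1 adjusted over the list alone. Its members included miR-8-5p at 0.84 ± 0.27 (adjusted p = 0.061), miR-275-5p at 0.71 ± 0.27 (adjusted p = 0.103), miR-275-3p at 0.64 ± 0.26 (adjusted p = 0.128) and miR-305-5p at 0.58 ± 0.27 (adjusted p = 0.158). In the immunity list 1 of 11 arms was called, miR-34-3p, and 4 adjusted over the list alone. The K box family had 0 of 8 arms called, and 1 adjusted over the list alone, with miR-13b-3p at 0.80 ± 0.26 (adjusted p = 0.061). No arm was called in the miR-9c cluster (0 of 3), the metabolism and growth list (0 of 13) or the sensory organ list (0 of 6), nor when adjusted over those lists alone. Members there included miR-9b-5p at 0.78 ± 0.34 (adjusted p = 0.158) and miR-14-3p, which acts in fat metabolism, at 0.58 ± 0.21 (adjusted p = 0.103). The same held for the let-7 complex (0 of 2), the miR-12 cluster (0 of 2), the miR-92 family (0 of 2) and muscle (0 of 1). In those, let-7-5p stood at -0.04 and miR-1-3p at -0.02, which turned to 0.03 and 0.05 with RPM as deposited, and miR-125-5p at -0.16. The camera test called 0 of 7 lists, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.670, or 0.764 with an estimated correlation. With all arms of each hairpin in the camera test the smallest adjusted p was 0.096. limma's fry test, which does not compare a list with other miRNAs, gave an unadjusted p of 0.033 for the miR-277 cluster and 0.034 for the miR-9c cluster. The midgut progenitor and sensory organ lists had a median below 0, a mean above 0 and a camera direction of down, and the metabolism and growth list had a median and mean above 0 with camera down.

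The arms of miR-958 had log2 changes of -0.43 ± 0.23 SE for miR-958-5p (adjusted p = 0.222) and 0.58 ± 0.26 for miR-958-3p (adjusted p = 0.158). The abundant miRNAs miR-956-3p, miR-10-5p, miR-263a-5p and miR-31a-5p did not pass, with log2 changes from -0.43 to -0.01. The value of miR-956-3p turned to 0.06 with RPM as deposited. Among the list members above, miR-34-5p, miR-317-3p, miR-8-5p and miR-13b-3p were called higher in the model of only these groups, with a filter of 100 RPM, and without Pe day 3 replicate 1. The model of only these groups with the replicate block called them higher too. It also called the list members miR-14-3p (limma adjusted p = 0.039) and miR-308-3p (log2 change 2.10, limma adjusted p = 0.028) higher.

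**Figure D1:**
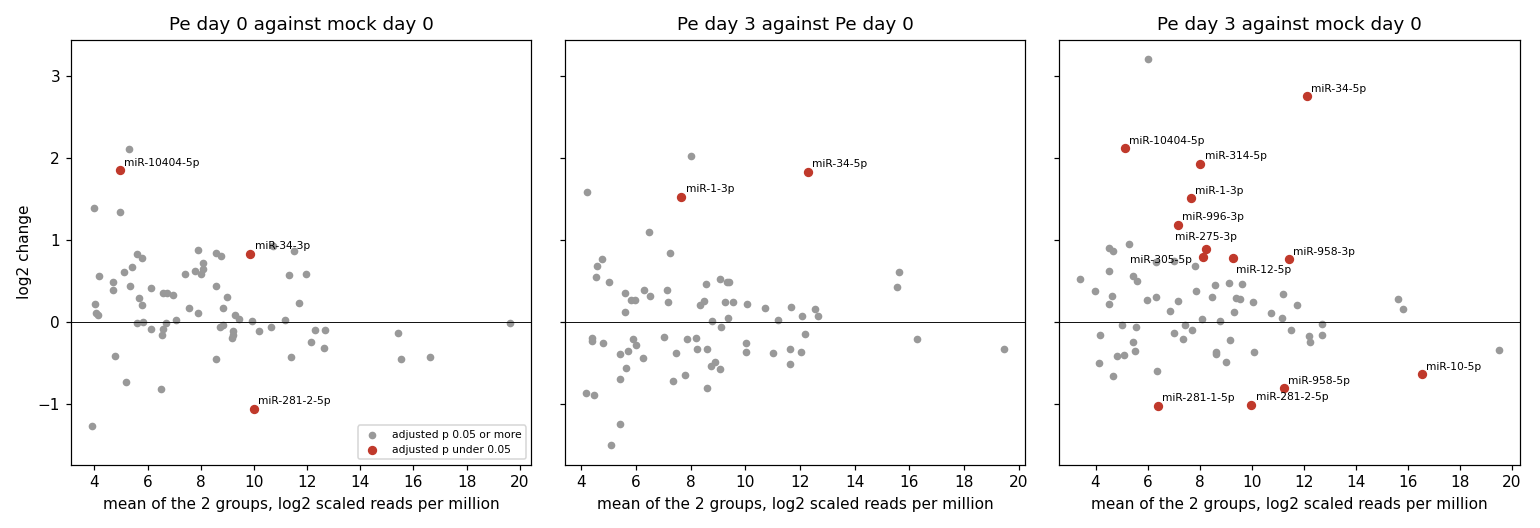
Log2 change (vertical axis) against the mean of the groups compared in log2 scaled RPM (horizontal axis) for 73 miRNAs in 3 contrasts. Red points passed adjusted p under 0.05 in limma: 3, 2 and 13 miRNAs, while most grey points lie within 1 log2 unit of 0.

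Pe day 3 was compared with Pe day 0 to describe the change from the first to the last stage, with the age of the flies changing too. miR-34-5p rose 3.55-fold (log2 change 1.83 ± 0.33 SE, 1.82 above the median, adjusted p = 0.00299), from 2193 ± 729 to 7726 ± 2369 scaled RPM (SD, n = 3). The muscle miRNA miR-1-3p rose 2.87-fold (log2 change 1.52 ± 0.28 SE, 1.51 above the median, adjusted p = 4.57e-04), from 104 ± 27.8 to 300.3 ± 17.5. Their hairpins lie on chromosome 3R from 10100936 to 10101034 and on 2L from 20487441 to 20487531, each in an exon of a long non-coding RNA on the same strand. Both were higher in 3 of 3 libraries than in any Pe day 0 library. miR-1 is a marker in the muscle list, so more muscle in the Pe day 3 samples could also give its rise. That was not tested.

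These were the 2 calls of 73 in limma, both higher, with 13 miRNAs at an unadjusted p under 0.05 and 18 whose libraries did not overlap (24.7%, 10% by chance). The total without the 5 most abundant miRNAs called 3 higher and 1 lower, and RPM as deposited 4 higher. Leaving out Pe day 3 replicate 1 gave 7 calls and leaving out Pe day 0 replicate 3 gave 4, and both miRNAs above were called in each.

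Other members of the miR-277 cluster did not pass: miR-277-5p had a log2 change of -1.25 ± 0.39 SE (adjusted p = 0.070), miR-317-3p of -0.52 ± 0.31 (adjusted p = 0.342) and miR-34-3p of -0.36 ± 0.23 (adjusted p = 0.360). In this cluster 1 of 5 arms was called, and 2 adjusted over the list alone. The immunity list had 1 of 11 called, and 3 adjusted over the list alone. The midgut progenitor list had 0 of 12 called, and 2 adjusted over the list alone, with miR-8-5p at -0.80 ± 0.27 (adjusted p = 0.070) and miR-263a-5p at 0.42 ± 0.21 (adjusted p = 0.270). The metabolism and growth list had 0 of 13 called, and 2 adjusted over the list alone. miR-9c-5p had a log2 change of -0.72 ± 0.29 (adjusted p = 0.157) in a cluster with 0 of 3 called. The sensory organ list had 0 of 6 called, with miR-996-3p at 0.83 ± 0.30 (adjusted p = 0.103), and the K box family 0 of 8, with miR-11-5p at -0.57 ± 0.24 (adjusted p = 0.163). The let-7 complex, the miR-12 cluster and the miR-92 family each had 0 of 2 called, among them let-7-5p at 0.52 ± 0.25 (adjusted p = 0.262) and miR-12-5p at 0.48 ± 0.23 (adjusted p = 0.231). The muscle list had its 1 tested member called, which is miR-1-3p itself. The camera test called 0 of 7 lists, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.385, or 0.689 with an estimated correlation. fry gave an unadjusted p of 0.017 for immunity, 0.026 for the miR-9c cluster and 0.047 for the miR-277 cluster. The immunity list holds the whole miR-277 cluster, miR-34-5p included, so the results for those lists are not separate. The K box family had a median below 0, a mean above 0 and a camera direction of down.

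Among the abundant miRNAs, miR-184-3p had a log2 change of 0.60 ± 0.20 SE (adjusted p = 0.070) and miR-956-3p of -0.33 ± 0.22 (adjusted p = 0.389). RPM as deposited (0.81) and the replicate block called miR-184-3p higher. miR-277-5p was called lower with the total without the 5 most abundant miRNAs, with the replicate block, and without Pe day 0 replicate 3 or Pe day 3 replicate 1. miR-8-5p and miR-11-5p were called lower without Pe day 3 replicate 1. The arms of miR-958 stood at -0.38 ± 0.23 for miR-958-5p and 0.18 ± 0.26 for miR-958-3p, neither past the threshold. miR-10-5p at -0.21 and miR-31a-5p at 0.07 did not pass either, and their sign turned with RPM as deposited and with the total without the 5 most abundant miRNAs, respectively.

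Pe day 3 was compared with mock day 0 to describe the last stage against the sucrose-fed mock gut, and the flies also differed in age. miR-34-5p, of a hairpin studied in the ageing fly brain, rose 6.72-fold (log2 change 2.75 ± 0.33 SE, 2.54 above the median, adjusted p = 8.27e-05), from 1147 ± 398 to 7726 ± 2369 scaled RPM (SD, n = 3). miR-10404-5p rose 4.33-fold (2.11 ± 0.44, 1.91 above the median, adjusted p = 8.71e-04), from the low mock mean given above to 59.9 ± 25.2. miR-314-5p rose 3.81-fold (1.93 ± 0.55, 1.72 above the median, adjusted p = 0.037), from 96.1 ± 31.8 to 423 ± 237. miR-1-3p rose 2.84-fold (1.51 ± 0.28, 1.30 above the median, adjusted p = 2.70e-04). The muscle signal given above is almost all miR-1-3p, so it is not a separate observation. The rise of miR-1-3p cannot be told apart from a larger share of muscle in the samples. miR-996-3p rose 2.27-fold (1.18 ± 0.30, 0.98 above the median, adjusted p = 0.0085).

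Smaller rises were those of miR-275-3p (log2 change 0.89 ± 0.26 SE), miR-305-5p (0.79 ± 0.27), miR-12-5p (0.78 ± 0.23) and miR-958-3p (0.76 ± 0.26), with adjusted p between 0.016 and 0.037. They lay 0.55 to 0.68 above the median. miR-305 is known to act in intestinal stem cells, and its hairpin lies beside that of miR-275 on chromosome 2L. The falls were miR-281-1-5p by 1.03 ± 0.33 and miR-281-2-5p by 1.02 ± 0.27, both from hairpins in an intron of Oda on chromosome 2R. miR-958-5p fell by 0.81 ± 0.23, and miR-10-5p, of a hairpin in the Antennapedia region, fell by 0.64 ± 0.22. Their adjusted p lay between 0.013 and 0.037, and they lay 0.85 to 1.23 below the median. The libraries of the groups did not overlap for any of these.

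In all 13 of 73 miRNAs passed limma's threshold, 9 higher and 4 lower, with 19 at an unadjusted p under 0.05 and 22 without overlap (30.1%, 10% by chance). The split was 5 higher and 5 lower with median-of-ratios factors, 10 and 0 with RPM as deposited, and 5 and 4 with the total without the 5 most abundant miRNAs. RPM as deposited ended the calls of all 4 miRNAs that fell. The total without the 5 most abundant miRNAs ended those of miR-275-3p, miR-305-5p, miR-12-5p and miR-958-3p, and median-of-ratios factors those of miR-314-5p, miR-305-5p, miR-12-5p and miR-958-3p. limma voom ended those of miR-314-5p and miR-958-3p. The authors' deposited table called 14, 8 higher and 6 lower, and 11 were shared, without miR-305-5p and miR-958-3p. Leaving out mock replicate 1 or Pe day 3 replicate 2 left 4 calls, and leaving out mock replicate 3 left 6. miR-34-5p, miR-10404-5p, miR-1-3p and miR-958-5p were called in all 9 fits without a library. miR-305-5p and miR-958-3p were called in 2 of those 9 fits, miR-314-5p in 4, miR-275-3p, miR-12-5p and miR-10-5p in 5, miR-996-3p and miR-281-1-5p in 6, and miR-281-2-5p in 7.

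The immunity list had 2 of 11 arms called higher, miR-34-5p and miR-958-3p, and 1 lower, miR-958-5p, with 3 adjusted over the list alone. The midgut progenitor list had 2 of 12 called higher, miR-275-3p and miR-305-5p, and 2 adjusted over the list alone, but the total without the 5 most abundant miRNAs ended both calls. The miR-277 cluster had 1 of 5 called, and 1 adjusted over the list alone, with miR-34-3p at 0.46 ± 0.23 (adjusted p = 0.201), miR-317-3p at 0.34 ± 0.31 (adjusted p = 0.512) and miR-277-3p at 0.27 ± 0.22 (adjusted p = 0.447). The sensory organ list had 1 of 6 called, miR-996-3p, and 1 adjusted over the list alone, beside miR-279-3p at -0.40 ± 0.30 (adjusted p = 0.442). The miR-12 cluster had 1 of 2 called, miR-12-5p, and 1 adjusted over the list alone. The metabolism and growth list had 1 of 13 called, miR-305-5p, and 0 adjusted over the list alone, with miR-278-3p, tied to insulin response in the fat body, at 0.95 ± 0.39 (adjusted p = 0.104). The miR-9c cluster (0 of 3), the K box family (0 of 8), the let-7 complex (0 of 2) and the miR-92 family (0 of 2) had no call in the main limma model. The authors' deposited table called 2 K box members lower, miR-2b-3p (log2 change -0.50, adjusted p = 0.024 there) and miR-11-5p (-0.61, adjusted p = 0.037 there). In the main model the K box member miR-308-3p stood at 3.20 ± 1.13 (adjusted p = 0.109) and was listed at 0 in mock replicate 3. The muscle list had its 1 tested member called, which is miR-1-3p itself. In the let-7 complex let-7-5p stood at 0.48 ± 0.25 (adjusted p = 0.231) and miR-125-5p at -0.60 ± 0.31 (adjusted p = 0.203). The camera test called 0 of 7 lists, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.457, or 0.857 with an estimated correlation. fry gave an unadjusted p of 0.0012 for immunity, 0.0020 for the miR-277 cluster and 0.048 for the midgut progenitor list. The median of all miRNAs stood at 0.21 with TMM here, and that of the midgut progenitor list lay 0.12 below it. Those p-values may thus reflect the scaling in part. Since the immunity list holds the whole miR-277 cluster, miR-34-5p included, the results for those lists are not separate. The K box and midgut progenitor lists had a median and mean above 0 with a camera direction of down. The metabolism and growth list had a median below 0 and a mean above 0 with camera down, and the sensory organ list the same with camera up.

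Of the abundant miRNAs, miR-956-3p stood at -0.34 ± 0.22 (adjusted p = 0.355) and miR-263a-5p at 0.28 ± 0.21 (adjusted p = 0.442). miR-184-3p stood at 0.15 ± 0.20 (adjusted p = 0.637), at -0.01 with median-of-ratios factors and at -0.05 with the total without the 5 most abundant miRNAs, but RPM as deposited called it higher at 0.43. The replicate block called miR-956-3p lower, and miR-308-3p was called higher with that block or without mock replicate 2. miR-278-3p was called without Pe day 0 replicate 2, and miR-11-5p was called lower with median-of-ratios factors, without Pe day 3 replicate 1 and in the deposited table. miR-31a-5p stood at -0.03 ± 0.21 (adjusted p = 0.922), and at 0.25 with RPM as deposited.

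**Figure D2:**
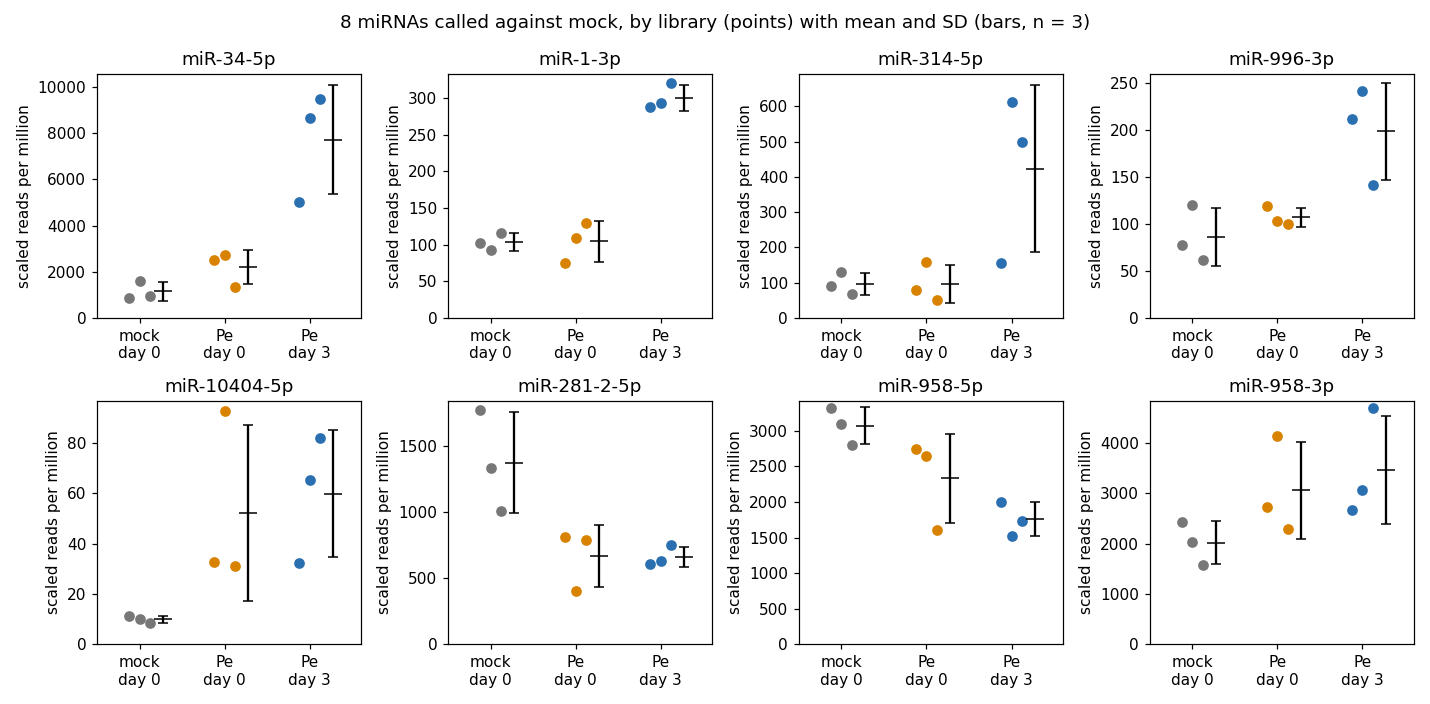
Scaled RPM (vertical axis, linear from 0) of 8 miRNAs in each library of the 3 groups (points), with the mean and SD of 3 libraries (bars). miR-34-5p averaged 1147 in mock and 7726 at Pe day 3, and miR-958-5p fell from 3073 to 1756 while miR-958-3p went from 2017 to 3467.

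The ratio of the arms of a hairpin within a library does not depend on the scaling, and was examined after the data were seen in 23 hairpins with both arms tested. The 3p to 5p ratio of miR-958 was 0.652 ± 0.085 in mock, 1.33 ± 0.30 at Pe day 0 and 2.01 ± 0.69 at Pe day 3 (SD, n = 3). The log2 ratio of 5p to 3p changed by -1.57 ± 0.34 SE from mock to Pe day 3 (limma adjusted p = 0.011) and stood at -1.01 ± 0.34 from mock to Pe day 0 (adjusted p = 0.165). The 5p to 3p ratio of miR-34 was 1.71 ± 0.47, 1.86 ± 0.63 and 8.47 ± 3.03, and its log2 changed by 2.29 ± 0.40 from mock to Pe day 3 (adjusted p = 0.0047). miR-996 changed by -1.27 ± 0.32 (adjusted p = 0.022). From Pe day 0 to Pe day 3, 3 hairpins passed, miR-34 (2.19 ± 0.40), miR-277 (-1.52 ± 0.37) and miR-996 (-1.21 ± 0.32). From mock to Pe day 0 limma called 0 of 23, with 3 at an unadjusted p under 0.05.

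**Figure D3:**
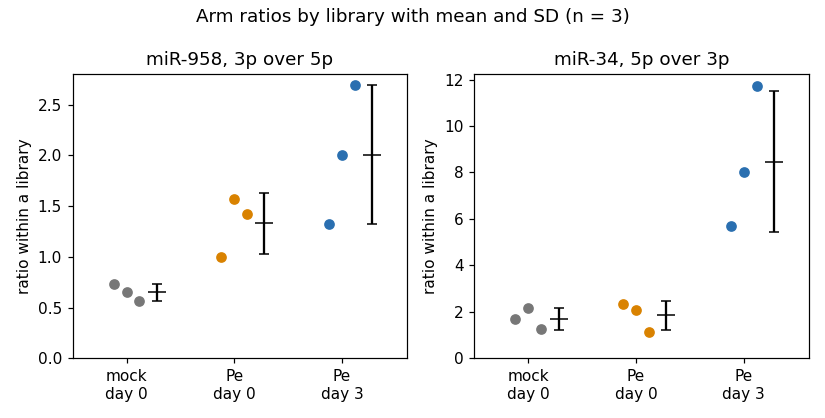
Ratio of the arms of miR-958 (3p over 5p) and miR-34 (5p over 3p) within each library (points, linear axis from 0), with the mean and SD of 3 libraries (bars). The pseudocount was added to each arm. The miR-958 ratio averaged 0.652 in mock and 2.01 at Pe day 3, and the miR-34 ratio 1.71 and 8.47.

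Among the 3 groups jointly, limma's F test called 10 of 73 miRNAs, with 25 at an unadjusted p under 0.05. They were miR-1-3p and miR-34-5p (adjusted p = 1.46e-04 for both), miR-10404-5p, miR-281-2-5p, miR-996-3p, miR-12-5p, miR-275-3p, miR-34-3p, miR-958-5p and miR-8-5p. The last was not called in any single contrast. The count was 18 with the replicate block, 6 with RPM as deposited, 6 with no filter and 5 with a filter of 10 RPM. Leaving out mock replicate 1, 2 or 3 left 3, 5 and 4 calls, and leaving out Pe day 0 replicate 1 or Pe day 3 replicate 2 left 5 and 4. Without Pe day 3 replicate 1 there were 19.

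The changes against mock at the 2 times share their mock libraries. Across 73 miRNAs, which are not independent replicates, their covariance was 0.246, beside 0.070 (0.025 to 0.136) in simulated groups without an effect against shared controls, a difference of 0.177. The correlation was 0.567, beside 0.495 simulated (0.214 to 0.718), and the share with the same sign 65.8%, beside 66.4%. One miRNA, miR-10404-5p, was called higher in both and miR-281-2-5p lower in both, where independent lists give 0.247 and 0.055, a value that leaves out the shared mock libraries. The correlation and the share with the same sign (56.1% to 76.7% simulated) lay within their simulated ranges. The mock libraries were not split, since 3 do not leave 2 for each comparison, so some or all of the excess in covariance may come from them. The covariance was 0.417 without mock replicate 2 and 0.162 without Pe day 0 replicate 2. The scarce miR-308-3p, not called in the main model, had high changes in both contrasts (log2 change 2.10 and 3.20) and so weighs on the covariance. Its change at Pe day 3 was 4.40 without mock replicate 2. The covariance without miR-308-3p was not computed.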

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

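The tests of the miR-34-5p rise, of scaling for miR-958, of the ovary signal and of splits within replicate numbers were chosen after the result was seen. Those of a general arm shift, of a single library and of other splits were written beforehand, although the patterns themselves were found in these data.

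The effect against mock differed between the days for the called pair of the direct comparison: by 1.52 on the log2 scale for miR-1-3p and by 1.83 for miR-34-5p, tested as Pe day 3 against Pe day 0. Signals outside the tested miRNAs and above the mock libraries were 96 reads of miR-989-3p and 45 of miR-311-3p in Pe day 0 replicate 3. miR-1007-5p had 41 reads over the Pe day 3 libraries (8, 17 and 16) and was listed at 0 in the other 6. The authors' deposited table calls it higher. miR-2535b-3p had 12 reads over the Pe day 0 libraries and was listed at 0 in mock.

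The rise of miR-34-5p at Pe day 3 was the largest among called miRNAs. Its lowest log2 change over 4 scalings was 2.55, which argues against scaling. More transcript of the whole miR-277 cluster would raise miR-277-3p and miR-317-3p alike, but miR-34-5p exceeded the nearer of them by 2.41 ± 0.59 SE, and miR-34-3p itself stood at 0.46. The age of the flies remains open, since there were 0 mock libraries of the older age, so age and treatment cannot be told apart. Processing or stability of the 5p arm, or a change in cell composition, was not tested.

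The arms of miR-958 moved apart at Pe day 3, with a change in the ratio of 5p to 3p of -4.62 SE. Scaling cannot give that, since it leaves a ratio within a library as it is, the pseudocount aside. A general shift of 5p against 3p arms would move other hairpins alike, but their median change was 0.033 with an SD of 1.11 over 22 hairpins, and 1 of them, miR-308, reached the miR-958 change. No single library carried it, since the smallest change without 1 library was -1.33. Treatment, the age of the flies, and reads assigned to the wrong arm were not tested as explanations.

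Pe day 0 replicate 3 held the ovary list, miR-318, miR-989 and miR-994, at 129 RPM. Depth does not account for it: at that library's rate the other 8 libraries would hold 323 reads of miR-989-3p, and they held 0. All 3 ovary hairpins had their highest RPM there, which restates the pattern, and miR-994 (7.27 RPM from 9 reads) hardly exceeded mock replicate 2 (5.51 RPM from 2 reads), so RNA of the ovary stays open. The others were miR-989 at 77.5 RPM and miR-318 at 44.4 RPM (27.5 RPM at most elsewhere), and among miRNAs outside the list, chosen after their values were seen, miR-31b stood at 149 RPM (11.1 at most elsewhere), miR-312 at 71.1 (8.89) and miR-311 at 36.3 (0), while miR-313 was listed at 0. No group of the design gives a biological explanation for 1 library, and none was tested.

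Other splits of the libraries were counted. For 3 against 3 there are 10 splits, too few for a share under 0.05. For Pe day 0 against mock the real split gave 3 calls and the highest other also 3, so 2 splits reached it. That other split sets mock replicates 1 and 3 with Pe day 0 replicate 3 and parts 1 numbered pair, while the splits that part all 3 pairs, the real one aside, gave 0. For Pe day 3 against Pe day 0 the real split gave 2 and the highest other 2, again 2 splits. For Pe day 3 against mock the real split gave 13 and the highest other 0, so 1 split reached it. For lists the real splits gave 0 and all 10 splits reached that in each contrast, with a highest other of 1, 0 and 0. Among the 3 groups, the real split was the only 1 of 100 to reach its 10 calls, so chance is unlikely there but not excluded. The highest other split gave 7 and keeps the 3 mock libraries together, and 10 other splits gave at least 1 call. These 100 splits are a sample of those possible and leave the possible pairing of mock and Pe day 0 aside. Among the 36 splits that give each group 1 library of each number, 1 reached the real 10 and the highest other gave 4. With the replicate block the real split gave 18 and the highest other 5.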

How the results depend on the processing

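Of the alternatives, the filter of 100 RPM, the pseudocounts, the block in only the groups compared and the deposited table were chosen after the data were seen. No called miRNA reversed under any alternative. miR-34-5p and miR-1-3p in both Pe day 3 contrasts and miR-10404-5p at Pe day 3 against mock kept their calls under all alternatives that give them a value, and the deposited table gives none for Pe day 3 against Pe day 0. Of 104 named results, the main model called 18. Over their 2158 values under the alternatives, 2028 kept their side of the threshold, 90 lost a call and 40 gained one. All 90 losses fell on the 18 called results, and most values that kept their side were of results not called, so 2028 does not measure how stable the calls were. For Pe day 0 against mock, 3 calls became 0 with RPM as deposited and 0 with no filter (22 at an unadjusted p under 0.05 in limma), 11 in only the groups compared, 1 with the replicate block, 11 with the replicate block in only the groups compared and 7 with a filter of 100 RPM. For Pe day 3 against Pe day 0, 2 became 4 with RPM as deposited, 4 with the total without the 5 most abundant miRNAs, 4 with no filter and 6 with the replicate block. Among the 3 groups, 10 became 6 with RPM as deposited, 6 with no filter, 5 with a filter of 10 RPM and 18 with the replicate block. The covariance of the changes against mock became 0.169 with no filter. Without 1 library the counts ran from 0 to 8 for Pe day 0 against mock, 2 to 7 for Pe day 3 against Pe day 0, 4 to 16 for Pe day 3 against mock and 3 to 19 among the groups, and the covariance from 0.162 to 0.417. The cause was not tested. Lists stayed at 0 calls under the alternatives run for them, the replicate block included. By correlation alone, the replicate numbers may pair Pe day 0 and mock but not the other groups. For Pe day 3 against mock the block moved 13 calls to 14. It ended the call of miR-958-3p and added miR-308-3p and miR-956-3p. The planned DESeq2 and quasi-likelihood count tests were not run, since the deposited values are RPM and the recovered reads had too few low values for the rule on them. Depth limits the scarce miRNAs: 72 of 145 listed above 0 fell below the filter, and Pe day 3 replicate 3 held 224873 reads.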

Other observations

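The ratios of neighbouring hairpins, miR-137-3p, the bootstrap interval and the reading of the neighbour test below were chosen after their values were seen, and both permutation tests before. Some arms of neighbouring hairpins did not change alike. miR-996-3p and miR-279-3p come from hairpins 3R 29217184 to 29217280 and 29215585 to 29215684, in exons of one long non-coding RNA, and from mock to Pe day 3 their log2 ratio changed by 1.57 ± 0.35 SE (limma adjusted p over 6 ratios = 0.0032). The difference is between these arms, since miR-996-5p stood at -0.07. The ratio of miR-275-3p to miR-305-3p changed by 0.98 ± 0.37 (adjusted p = 0.036), but miR-305-5p rose beside miR-275-3p in the main model, so the ratio depends on the arm chosen, although the arms of miR-305 did not differ past the threshold (0.88 ± 0.33, adjusted p = 0.082). The ratio of miR-12-5p to miR-283-5p stood at 0.54 ± 0.28 (adjusted p = 0.092) and that of miR-281-2-5p to miR-281-1-5p at 0.02 ± 0.28 (adjusted p = 0.934). The neuronal miR-137-3p was listed in all 3 mock libraries and in Pe day 0 replicates 1 and 3, and at 0 in the Pe day 3 libraries, with at most 12 reads in any library.

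A hypothesis written before its test was that the arms of a hairpin change together at Pe day 3. Across 23 hairpins, which are not independent replicates, Pearson's r between the changes of the 5p and 3p arms was -0.059 (permutation p = 0.580, one-sided) and Spearman's rho -0.119 (permutation p = 0.704). Without miR-34 and miR-314, the hairpins farthest from the median, r was 0.026. The bootstrap interval of r, -0.41 to 0.21, was added after the p was seen. It resamples hairpins and does not allow for the error of each estimated change, which pulls r toward 0. Its upper bound thus speaks against a strong relation of the estimated changes only, and one between the true changes is not excluded.

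A second hypothesis was that hairpins within 10 kb on the same strand change alike. The mean absolute difference in log2 change was 0.948 over 12 neighbouring pairs and 0.772 in permuted pairs (permutation p = 0.780, one-sided, 100000 permutations). The bound written beforehand, a p of 0.05 or more, was met, but a p that misses the threshold does not exclude a relation in 12 pairs, of which 2 hold miR-34. That reading was chosen after the p was seen, and the question stays open.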
